A study of Mus musculus with 2 samples.

How the data were processed

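Striatal RNA of 1 wild-type mouse sample and 1 sample lacking the dopamine D2 receptor gene (Drd2-/-) was measured on Affymetrix expression arrays, 1 array each. Per the labels, both came from untreated C57BL/6 males aged 2 months, the striatum was taken by hand under a dissecting microscope, total RNA was extracted with Trizol, and biotin-labelled cRNA was made by Affymetrix's standard method. Whether each sample was 1 animal or a pool was not given in the sources used here. Nothing in the sources used here states how the Drd2-/- allele was made.

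The authors deposited 1 signal intensity per probe set and array, on a linear scale and scaled per array, per the file headers. From the values, the mean after trimming the lowest and highest 2% was 500.0 on the wild-type array and 499.7 on the Drd2-/- array, so the overall scale of the arrays was set equal before deposit. Per the file headers, the authors also deposited for each array a detection p-value with a call of present, marginal or absent. The authors' comparison table further held a Signal Log Ratio on the log2 scale with its lower and upper limits, a change p-value and a change call. That change p-value compares the probes of 1 array with those of the other, not replicate animals, and is not printed here. The software, its version and its settings were not given in the sources used here.

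Groups came from the sample labels of the value table. At all 45101 probe sets the value table and the comparison table held identical signals under opposite genotype names, while only 91 probe sets had equal signals under the same name. Detection calls were therefore attached to the array whose signal stood beside them, and the authors' log ratios and change calls were turned to Drd2-/- over wild type as the sample labels define it. If the comparison table's column names were right instead, every sign in the text would be reversed.

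The arrays held 45101 probe sets, of which 64 were manufacturer's controls. Of the other 45037, 34945 were paired with exactly 1 gene in the platform annotation, 932 with several and 9160 were unnamed there. An Entrez number found in the RefSeq table of mouse assembly GRCm38.p6 backed 34741 of the 34945, and no symbol needed updating. That table was used only for names and for the order of genes beside Drd2. A gene was represented by the probe set with the highest mean log2 signal among those paired with that gene alone, which gave 18193 genes. A gene counted as detected when its representative was called present on at least 1 array: 12588 genes, of which 11515 were present on both arrays, 633 only on the wild-type array and 440 only on the Drd2-/- array. For genes present on 1 array the ratio is a bound, computed against the higher of the dim array's lowest present signal (5.0 in wild type, 5.9 in Drd2-/-) and the probe set's own signal, and set to 0 where the bound would cross it. Signals below 0.1 were set to 0.1 before logs were taken.

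The measure was log2 of the Drd2-/- signal over the wild-type signal. With 1 array per genotype there is no test, no standard deviation and no p-value, and genes were counted by size alone, at 2-fold. The number of arrays limits the precision of every value. The medians of 24 gene lists were set against 10000 random lists of as many detected genes, matched on mean log2 signal in 20 bins, and list members were counted at 1.5-fold. Where a list's median lay outside the central 95% of its random lists this describes these 2 arrays only. As a check within the arrays, the direction of a gene's second brightest detected probe set was compared with that of its representative, with Wilson 95% intervals over genes. Genes 20 to each side of Drd2 were examined because DNA beside a targeted gene can derive from another strain.

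Groups, lists, measures, alternatives and the rule for named genes were fixed before the data were examined. The rule named Drd2; the 12 highest and 12 lowest ratios among genes present on both arrays with a mean log2 signal at or above the median of 9.45; up to 6 genes in each direction present on 1 array and absent on the other with a bright signal of at least 704 units; Cryab and up to 4 detected members of each list with the largest absolute ratio; and up to 5 neighbours of Drd2 at least 1.5-fold apart. Predicted genes, RIKEN clones and unnamed probe sets were counted and not named. Gfap, Vim, Penk, Gpr6, Tac1, Th, Fos, Nrgn, Lamp5, Mef2c, Folr1 and Clic6 fell outside the rule and were chosen after their values were seen, as were the members named from 2 gene sets used in the closing tests. Tnf, Il6, Ifng, Nos2 and Ccl2 also fell outside it and are named only as not detected.

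The alternatives were median centring of the ratios, quantile normalization, intensity-dependent centring (a lowess curve of ratio on mean log2 signal with a span of 0.2), 32 signal units added to both arrays, only genes present on both arrays, no filter on detection, the median over a gene's detected probe sets, leaving out probe sets with shared sequence, and the authors' Signal Log Ratio in place of the ratio of signals. Movements of single genes under these alternatives were set against the spread of genes of like signal, the scaled median absolute deviation of the ratios of genes next to them in mean signal. The counting and list steps were tested on simulated data for the Drd2-/- against wild-type comparison with 18193 genes. Of 100 genes given a 3-fold difference 97.0%, and of 100 given a 1.5-fold difference 7.0%, came out at least 2-fold apart in the right direction. Of 11315 genes given none, 0.583% came out at least 2-fold apart. Of 50 simulated lists of 15 genes moved by -0.4, 100% lay below the random range, and 4.0% of 50 lists left alone lay outside it. The simulation kept the measured representative probe sets and detection calls, so neither step was tested. It added independent noise centred on 0 to each probe set, so its rates need not hold for the 2 measured arrays. Computations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9.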

Results

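Gene expression was measured in the striatum, a brain region rich in D2 receptors, of 2-month-old male C57BL/6 mice with and without the receptor gene Drd2. There was 1 array for the wild type and 1 for the Drd2-/- genotype, so no value has a replicate error and none of the differences was tested. Of 45101 probe sets, 57.9% were called present on the wild-type array and 58.7% on the Drd2-/- array. The median signal was 104 units in wild type and 133 units in Drd2-/-. Across the 11515 genes present on both arrays, Pearson's r of the log2 signals was 0.979, a correlation over genes, which are not independent replicates. The hybridization controls differed by a median log2 ratio of 0.02 and the poly-A controls by -0.00. The 3' to 5' signal ratios of the control messages of Actb, Gapdh, Pcx and Tfrc were 1.01-fold, 1.05-fold, 1.30-fold and 1.12-fold apart between the arrays.

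The comparison asked which striatal transcripts differ when the D2 receptor is missing, with inflammation and the small heat shock protein Cryab as points of interest known for this study. Drd2 itself, measured by a single probe set, read 3234.8 units and present in the array labelled wild type, and 27.4 units and absent in the array labelled Drd2-/-. From these signals it was 118-fold lower in the Drd2-/- array, a log2 ratio of -6.88. Where this probe set lies relative to the deleted part of the gene is not given in the sources used here. In the authors' deposited table the log ratio of Drd2, turned to the sample labels, was -6.9 with limits of -8.3 and -5.4. The size of the difference is therefore not firm as a bound. The direction of this and every later value follows the sample labels. The column names of the authors' comparison table give the same signals to the opposite genotypes and would reverse every sign.

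Among the brighter genes, the highest ratios in the Drd2-/- array belonged to Fgf14, a modulator of neuronal sodium channels, at 2.33 on the log2 scale (404 units in wild type, 2032 in Drd2-/-), and to the noncoding transcript Snhg14 at 1.81. Kif5b, a kinesin motor subunit, followed at 1.55, and all 5 of its other probe sets were also higher, between 1.15 and 2.09. The long noncoding nuclear RNA Malat1 read 1.39, with 6 of 6 other probe sets higher. Anxa3 read 1.42, Arhgap5 1.39, the peptidase neprilysin (Mme) 1.35, the AMPA receptor subunit Gria3 1.34, Spock3 1.33, Sh3bgrl 1.32, the COP9 signalosome subunit Cops2 1.28 and Trim23 1.28. The second probe sets of Mme and Gria3 gave smaller ratios of 0.79 and 0.80, and that of Cops2 a larger one of 2.07. The other 3 probe sets of Fgf14 gave 0.14, 0.19 and 2.71, the value of 0.19 from the one designed on a full-length message, so the size for this gene depends on the probe set.

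The lowest ratio among the brighter genes was that of Cryab, which encodes αB-crystallin, a small heat shock protein. Its signal was 6222.4 units in wild type and 2961.8 in Drd2-/-, 2.10-fold lower (log2 ratio -1.07), and its second detected probe set gave -1.27. In the authors' deposited table its 2 detected probe sets, turned to the sample labels, had log ratios of -1.2 and -1.4, both called decreased. Camk2a, a kinase subunit abundant in forebrain neurons, was 2.01-fold lower. On the log2 scale Vxn read -1.06, Wwc2 -1.01, Abr -0.90, Igdcc4 -0.86, the lipid peroxidase Gpx4 -0.85, Tmem178 -0.85, the AMPA receptor auxiliary subunit Cacng3 -0.81 and Cdc42ep2 -0.77. Arhgap39 (-0.91) and Daam1 (-0.80) rest on 1 probe set each, since the other detected probe sets of both genes were higher in Drd2-/-, and Camk2a and Wwc2 had other probe sets of either direction. In the authors' deposited table, turned to the sample labels, several of these representative probe sets had smaller log ratios: -0.2 for Wwc2 and Arhgap39 and -0.3 for Abr, all called unchanged, and -0.4 for Camk2a, Igdcc4 and Gpx4. Vxn read -1.3 there, below the -1.2 of the representative probe set of Cryab, so which of them is lowest is not settled. Some bright genes had a representative probe set present in wild type and absent in Drd2-/-. After Drd2, their bounds from the signals were -0.76 for Kcnip3, -0.67 for Rusc2, -0.36 for Abl1 and -0.18 for Dgcr2. No named gene of that brightness had a representative present in Drd2-/- and absent in wild type. These bounds are not firm: the authors' deposited table, turned to the sample labels, gives the same probe sets -0.4 for Kcnip3 (limits of -0.6 and -0.1), -0.5 for Rusc2, -0.3 for Abl1 and -0.1 for Dgcr2, all called unchanged. Kcnip3, Rusc2 and Dgcr2 also had other probe sets present on both arrays, at -0.66 for Kcnip3, -0.46 for Rusc2, and -0.71 and -0.44 for Dgcr2. Of those, the authors' deposited table calls that of Kcnip3 decreased (-0.6) and the others unchanged. In the same array cortical neuron markers were lower (median -0.36), and whether this bears on the genes named here was not tested.

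**Figure D1:**
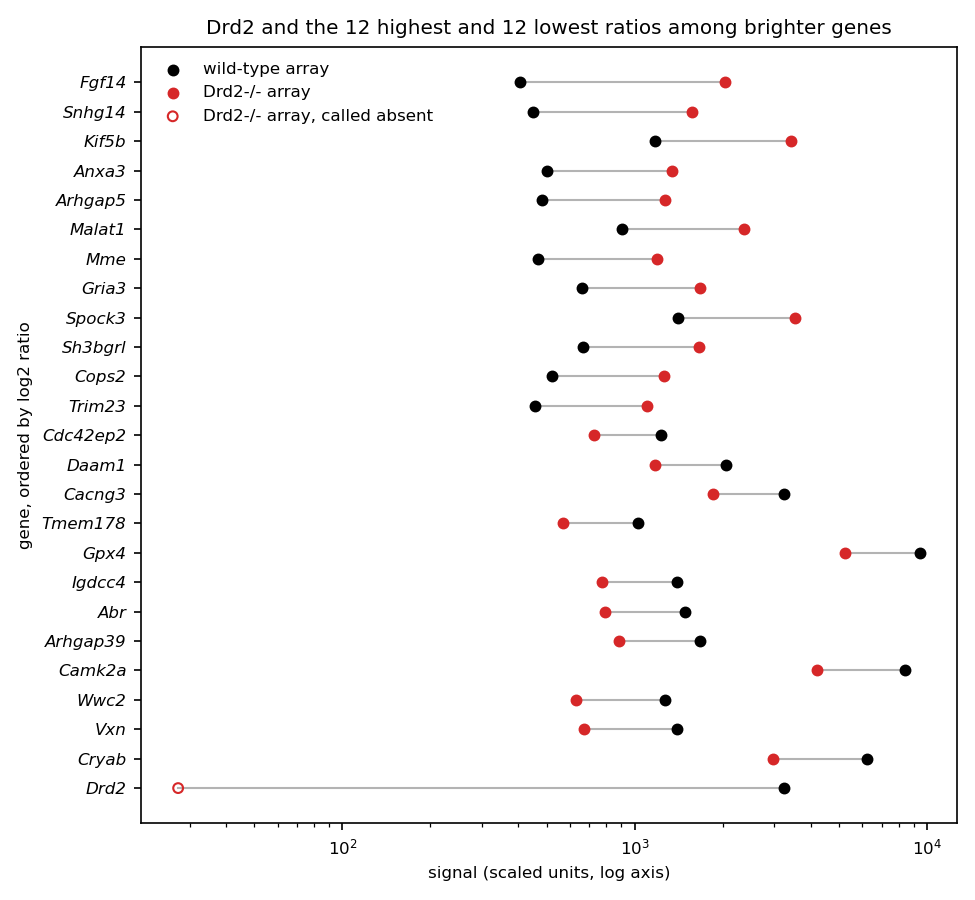
Signal in scaled units (horizontal log axis) of Drd2 and the genes with the 12 highest and 12 lowest ratios, 1 point per array, black for wild type and red for Drd2-/-, with an open point for a signal called absent. Drd2 reads 3234.8 units in wild type and 27.4 in Drd2-/-, and Cryab 6222.4 and 2961.8.

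Of 12588 detected genes, 393 were at least 2-fold higher and 103 at least 2-fold lower in the Drd2-/- array, and 87.5% lay within 1.5-fold. Higher genes thus made up 79.2% of those at least 2-fold apart, 78.3% after median centring (382 higher, 106 lower), 48.1% after quantile normalization (221 and 238) and 54.6% after intensity-dependent centring (253 and 210). The last 2 scalings move the counts toward balance whatever the cause, so the origin of the excess stays open. Most of the higher genes lay among dim genes: of 4 equal groups by mean signal, the dimmest held 276 higher and 84 lower genes and the brightest 10 and 2. Over genes present on both arrays the median log2 ratio was -0.07, with quartiles of -0.24 and 0.18. Of 148 genes at least 2-fold higher that had a second detected probe set, that probe set was also higher in 94.6% (Wilson 95% interval 89.7 to 97.2), and of 15 lower genes in 73.3% (48.0 to 89.1), against 68.4% for all 5836 genes with 2 detected probe sets. The 68.4% was matched neither on the size of the ratio nor on signal. By definition the second probe set is the dimmer one, and dim genes leaned higher in Drd2-/- (median log2 ratio 0.06 in the dimmest group, -0.14 in the brightest). In the authors' deposited table, turned to the sample labels, 1106 detected genes were called increased and 714 decreased by their representative probe sets, and over all probe sets, unnamed ones included, the counts were 4355 and 1118.

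**Figure D2:**
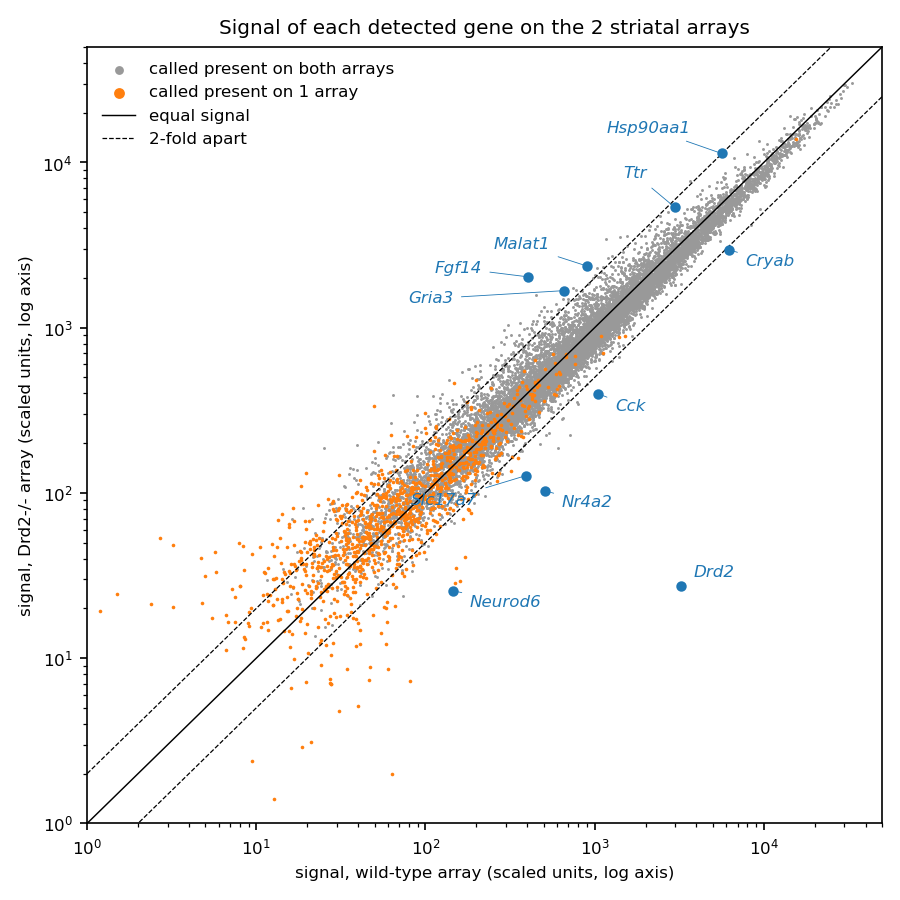
Signal of each detected gene on the wild-type array (horizontal) and the Drd2-/- array (vertical), both in scaled units on log axes from 1 unit (4 genes lie below the axes), with lines for equal and 2-fold different signals. Drd2 stands farthest from the line of equal signal among the labelled genes, and the 393 genes at least 2-fold higher lie mostly at low signal.

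Small heat shock and chaperone genes were lower as a group in the Drd2-/- array. The median of 14 detected members was -0.32, below the central 95% of matched random lists (-0.23 to 0.06; percentile 0.03), and 12 members were below 0. Besides Cryab, the inducible Hsp70 genes Hspa1b and Hspa1a read -0.75 and -0.57 and Hspb1 read -0.56. The authors' deposited table, turned to the sample labels, calls Hspa1b (-0.8) and Hspb1 (-0.5) decreased and Hspa1a (-0.3, limits of -1 and 0.3) unchanged. The cytosolic Hsp90 gene Hsp90aa1 went the other way at 1.01, with all 3 other detected probe sets higher. Cortical neuron markers (median -0.36) were lower in the same array.

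Of 29 measured inflammatory mediators 12 were detected, and these did not stand apart from random lists. Their median was 0.11 (percentile 85.3, random range -0.23 to 0.28). Tnf, Il6, Ifng, Nos2 and Ccl2 were among those called present on neither array, so the median does not cover them. The sole detected member at least 1.5-fold apart was Cybb, a subunit of the phagocyte NADPH oxidase, at 0.76 and 32 to 54 units. The authors' deposited table calls Cybb unchanged, at 0.8 with limits of -0.3 and 1.9. The chemokine Cxcl2, at 11.5 and 16.5 units, has no settled direction: the bound from the signals was 0.52, and the authors' deposited table gives -0.3 with limits of -1.2 and 0.5. Hmox1 read -0.43 and the chemokine Cx3cl1 -0.34. Microglia markers had a median of -0.18 over 19 members (percentile 9.11; random range -0.22 to 0.10), with Ptprc at 0.76 (0.5 in the authors' deposited table) and Cx3cr1 at -0.44, Fcer1g at -0.37 and Itgam at -0.36.

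Reactive astrocyte markers were lower in the Drd2-/- array, with a median of -0.23 over 17 detected members against a random range of -0.20 to 0.22 (percentile 1.24). Of these, 3 were at least 1.5-fold lower and none as much higher. Lcn2, a secreted iron-carrier-binding protein, was at most -1.15 from a dim signal, the interferon-induced GTPase Gbp2 read -0.77 and S100a10 -0.65. In the authors' deposited table, turned to the sample labels, Lcn2 alone of these 3 stayed past 1.5-fold at -1.3, with Gbp2 at -0.3, called unchanged, and S100a10 at -0.4. The intermediate filament genes Gfap and Vim read -0.35 and -0.49. The list shares Hspb1 with the chaperone list, and its median lay inside the random range, at -0.10, when genes detected on neither array were included, and at its edge with the median over probe sets (-0.17). Cortical neuron markers were lower in the same array here too (median -0.36). Homeostatic astrocyte markers had a median of -0.09 (15 genes, percentile 74.3), with Mlc1 at -0.42, Sox9 at -0.35, Ntsr2 at -0.30 and the water channel Aqp4 at 0.42.

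Markers of the principal striatal neurons differed little between the arrays. Markers of D2-type projection neurons, the cells that normally carry the receptor, had a median of -0.09 over 8 genes (percentile 67.2), and none was 1.5-fold apart. Their abundant transcripts Penk and Gpr6 read -0.01 and -0.06, and Plxdc1 was the farthest at -0.51, followed by Adk at -0.18, Grik3 at 0.12 and Rgs4 at -0.12. D1-type markers had a median of -0.12 over 9 genes (percentile 46.7): the dynorphin precursor Pdyn read -0.82, Sfxn1 -0.43, Drd1 -0.28, Eps8 0.24 and Tac1 -0.07, with Pdyn at -0.5, called unchanged, and Eps8 at -0.2 in the authors' deposited table. Markers shared by both types had a median of -0.06 over 19 genes (percentile 95.3), which lay between -0.10 and 0.10 over the alternatives. They included the cannabinoid receptor Cnr1 at 0.67, the GABA-synthesizing enzyme Gad2 at 0.48, Pde10a at 0.43 and Pde1b at -0.43. The other probe sets of Pde10a ran from -0.03 to 0.61, and that of Gad2 gave 0.15. For the representatives the authors' deposited table gives 0.2 for Gad2 and Pde10a and -0.2 for Pde1b, all called unchanged. Interneuron markers had a median of -0.18 over 13 genes (percentile 12.8), with the cholecystokinin precursor Cck at -1.40, the choline transporter Slc5a7 at 0.41, Lhx8 at -0.38 and Sst at -0.37. Since cortical neuron markers were lower in the same array (median -0.36), the Cck difference cannot be assigned to interneurons.

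Ionotropic and metabotropic receptor genes for glutamate and GABA were higher in the Drd2-/- array, with a median of 0.29 over 16 genes against a random range of -0.24 to 0.07 (percentile 99.98). Gria3 read 1.34 (0.80 by its other probe set) and the NMDA receptor subunit Grin2a at least 1.33 from a dim signal. The GABA-A receptor subunit Gabra2 read 0.99, with its other detected probe sets at 0.42 and 0.67. Gria2 read 0.60, with its other probe sets at 0.86 and 1.23. In all, 4 members were at least 1.5-fold higher and none as much lower, though the authors' deposited table gives the representative probe set of Gria2 0.4, under 1.5-fold, and Grin2a 1.1, called unchanged. The median stayed between 0.26 and 0.35 in every alternative run, the scalings included. Cortical neuron markers (median -0.36) were lower in the same array.

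Genes of dopamine handling and signalling had a median of -0.13 over 19 genes (percentile 26.0). The vesicular monoamine transporter Slc18a2 read 1.36 at 53 to 137 units, Drd3 at least 0.68 near background, the calcium sensor Ncald -0.73 and the potassium channel Kcnj9 -0.68, while the dopamine-synthesizing enzyme gene Th read 0.12. The other detected probe sets of Kcnj9 gave 0.54 and -0.22, so its direction depends on the probe set, and the authors' deposited table gives -0.4 for Kcnj9, called unchanged, and -0.5 for Ncald, called decreased. Drd3 was also called unchanged there, at 1.2 with limits of -0.1 and 2.5, so its bound is not firm. Immediate early genes had a median of -0.09 over 21 genes (percentile 48.9). Nr4a2 was 4.95-fold lower (-2.31), with its 3 other detected probe sets between -1.88 and -1.14. Egr2 read -1.20, but -0.58 by its second detected probe set and -0.7 in the authors' deposited table for the first. Npas4 and Nr4a1 were higher at 0.71 (0.5 in the authors' deposited table) and 0.57 (0.4 there, called unchanged), and Fos read -0.09. In the same array cortical neuron markers were lower (median -0.36), so the difference in Nr4a2 cannot be assigned to neuronal activity or genotype.

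Markers of tissue adjoining the striatum were examined because the piece was cut by hand. Cortical excitatory neuron markers were lower in the Drd2-/- array, with a median of -0.36 over 12 genes against a random range of -0.23 to 0.22 (percentile 0.02). Neurod6 read -2.51, Tbr1 at most -2.12 (-1.1 in the authors' deposited table), the vesicular glutamate transporter Slc17a7 -1.62 and Rtn4rl2 -0.82 (-0.5 in the authors' deposited table, called unchanged), all at most 392 units in wild type. Nrgn, Lamp5 and Mef2c, which read 5189, 4727 and 3100 units in wild type, gave 0.08, 0.17 and 0.05. These arrays cannot tell whether those bright signals came from cortex or from the striatum itself. Over the 9 of 12 members present on both arrays the median was -0.11 (percentile 37.0), and with no filter on detection -0.18 (percentile 6.16), both inside their random ranges. The first of these leaves out members for not being present in Drd2-/-. Septal, pallidal and thalamic markers had a median of 0.00 over 13 genes (percentile 45.9), with Slc17a6 at most -2.27, Rora 0.75, Ramp3 -0.75 and Gbx2 at least 0.58 from the signals. The authors' deposited table gives Slc17a6 -2.7 (limits of -4.9 and -0.4), Ramp3 -0.3 and Gbx2 0.3, all called unchanged. The bounds for Slc17a6 and Gbx2 are therefore not firm. Choroid plexus and ependymal markers had a median of -0.04 over 10 genes (percentile 35.1). Among them Ttr read 0.84, with 3 of 3 other probe sets higher, and Kcne2 at least 1.78 from signals near background, whereas Mia was at most -0.90 from the signals, Foxj1 read -0.77, Folr1 0.02 and Clic6 0.05. In the authors' deposited table, turned to the sample labels, all of Kcne2 (0.6), Mia (-0.4, limits of -0.7 and -0.1) and Foxj1 (-0.4) were called unchanged, so the bounds for Kcne2 and Mia are not firm.

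**Figure D3:**
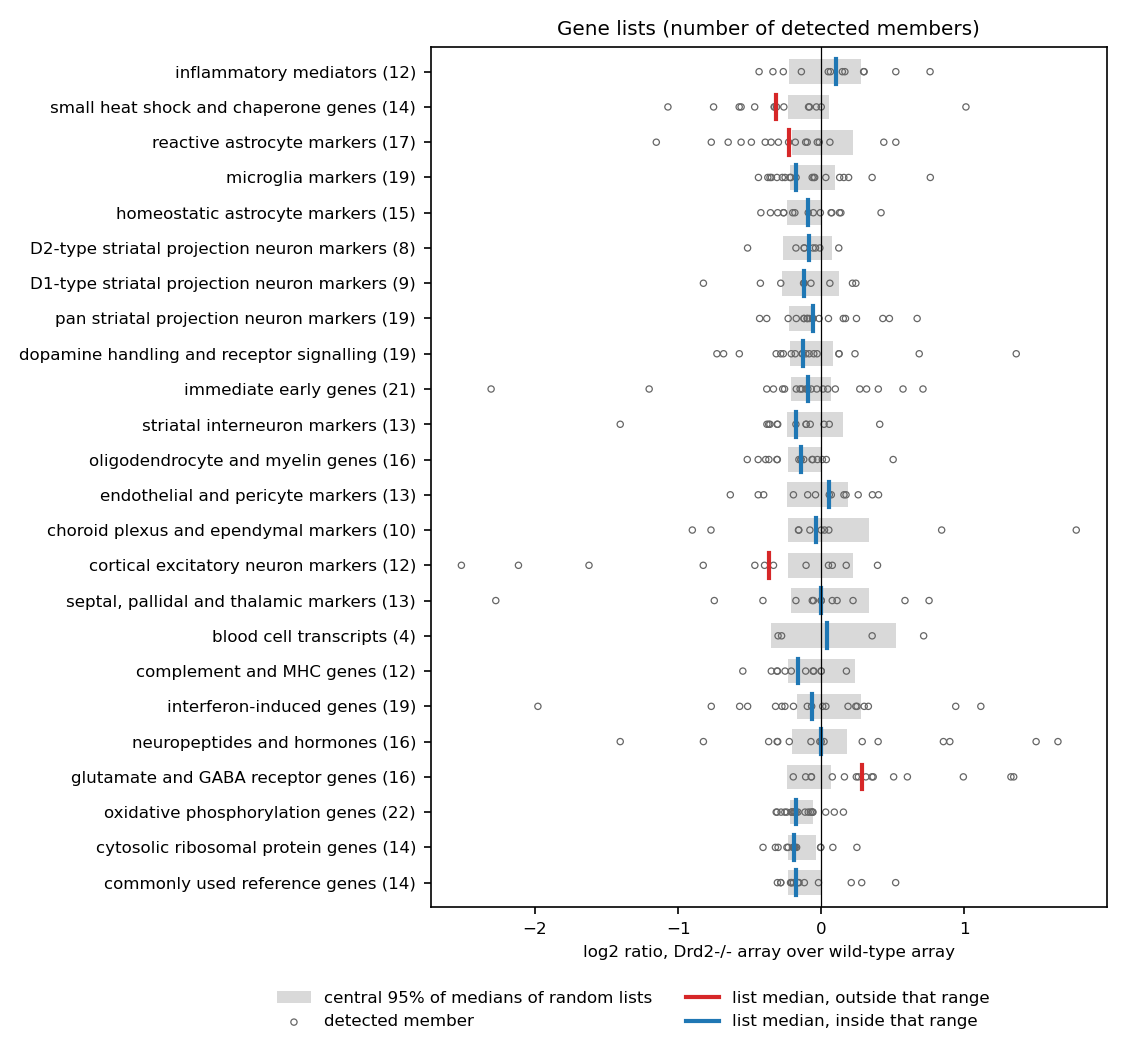
Log2 ratio of the Drd2-/- over the wild-type array (horizontal axis) for detected members of 24 gene lists (open circles), with each list's median (vertical bar) and the central 95% of medians of matched random lists (grey). Medians of the chaperone (-0.32), reactive astrocyte (-0.23), cortical neuron (-0.36) and glutamate and GABA receptor (0.29) lists lie outside that range.

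Oligodendrocyte genes had a median of -0.14 over 16 genes (percentile 40.8), with Opalin at -0.52, Mog at -0.44, Cnp at -0.39 and Ermn at 0.50. Endothelial and pericyte markers had a median of 0.06 over 13 genes (percentile 85.9), with Vwf at -0.64, Cdh5 at -0.44, Kdr at -0.40 and Abcb1a at 0.40. The bright housekeeping lists all lay slightly below 0, inside their random ranges: oxidative phosphorylation genes at -0.18 (22 genes, percentile 19.1; Uqcrfs1 -0.31, Cox6c -0.31, Sdhb -0.28, Ndufv1 -0.25), ribosomal protein genes at -0.19 (14 genes, percentile 15.6; Rpl27 -0.41, Rps3 -0.32, Rps14 -0.30, Rpl7 0.25) and reference genes at -0.18 (14 genes, percentile 19.3; Tfrc 0.52, Gusb -0.31, Tubb5 -0.28, Tbp 0.28). Of all members of the lists in this paragraph, Vwf alone was at least 1.5-fold apart, and the authors' deposited table gives it -0.1 with limits of -0.5 and 0.3.

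Genes beside Drd2 on chromosome 9 were examined in the order of the reference annotation. Of the 40 genes, 20 on each side, 17 were measured and 11 detected. Of these 11, 5 were at least 1.5-fold apart (45.5%, against 12.5% of all detected genes). The 12.5% was not matched on signal, although large ratios lay mostly among dim genes. Bco2, a carotenoid-cleaving enzyme, was at most -1.26 and Pts, an enzyme of tetrahydrobiopterin synthesis, read -1.16, whereas Zbtb16 read 0.70 with both other probe sets higher, the serotonin receptor subunit Htr3a 0.69 (0.1 in the authors' deposited table) and a predicted gene 0.67. The count was 3 after quantile normalization, after intensity-dependent centring and from the authors' log ratios. Cryab was not among these 40 genes, and how far it lies from Drd2 was not examined. Whether DNA from another strain bears on the Cryab difference was therefore not tested.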

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

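The test on spiked-in controls and the spread used to weigh the nuclear RNA test were chosen after the results were seen; the tests of centring and of probe design in the next paragraph, and the nuclear RNA set itself, were fixed before their results were seen. The 9160 probe sets without a gene name entered no comparison: of 3980 detected, 1315 (33.0%) were at least 2-fold higher and 33 at least 2-fold lower in the Drd2-/- array, against 8.40% of named genes higher when matched to them on mean log2 signal in 20 bins, and 3.12% of all named genes. Their median log2 ratio was 0.58, and their median mean log2 signal was 6.75, against 9.26 for named genes. Named genes entered by their brightest probe set alone, whereas every detected unnamed probe set was counted. Other probe sets of named genes were not compared, so whether the excess is particular to unnamed ones stays open.

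The excess of higher over lower signals was 3.82-fold for named genes. For unnamed probe sets a scaling difference that varies with signal is not the whole cause. Intensity-dependent centring changed the counts from 1315 higher and 33 lower to 930 higher and 90 lower, still a ratio of 10.3. Probe sets designed on expressed sequence tags are not the whole cause for named genes, as those designed on full-length messages gave a ratio of 3.14 (116 higher, 37 lower). For named genes a scaling difference stays open: the near-equal counts after centring do not bear on it, since centring moves them toward balance whatever the cause, and 12 dim spiked-in control probe sets had a median of 0.086 (quartiles -0.05 and 0.25), short of the curve's 0.35 but too scattered to decide. More nuclear RNA in the Drd2-/- array stays open too, along with genotype: 11 nuclear noncoding RNAs other than Malat1 and Snhg14 had a median of 0.13 (percentile 97.4 of matched random lists, random range -0.25 to 0.13, 9 of 11 above 0), under both the 0.58 the explanation needed and the 0.3 set to count against it, but they ran from Rian at -0.57 to Kcnq1ot1 at 1.67, and the 0.67 between their quartiles exceeds the gap of 0.45.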

How the results depend on the processing

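The direction by the comparison table's column names and the restriction to probe sets designed on full-length messages were chosen after seeing the data; the other alternatives were planned. Every ratio rests on 1 array per genotype, and ratios of dim genes depend on the background under both signals. Drd2 read -5.78 with 32 signal units added and had no value when only genes present on both arrays were kept; by the comparison table's column names it was 6.9, which reverses it by construction.

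The number of genes at least 2-fold higher was 393 and lower 103. It became 382 and 106 after median centring, 221 and 238 after quantile normalization, 253 and 210 after intensity-dependent centring, 177 and 27 with 32 units added, 259 and 42 over genes present on both arrays, 1781 and 868 with no filter, and 116 and 37 on full-length designs. The authors' Signal Log Ratio gave 59 lower genes, and by its column names 59 higher and 319 lower. The cause was not tested, except that filters and designs change how many genes enter and exchanged names exchange the counts.

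The cortical median moved to -0.11 over genes present on both arrays and was -0.18 with no filter. Both lay inside their random ranges (percentiles 37.0 and 6.16). By construction the first set keeps 9 of 12 members and leaves out those not present in Drd2-/-, Tbr1 among them. Agreement of a second probe set for higher genes was 94.6%, and became 73.8% with no filter, 84.5% without shared-sequence probe sets, 98.6% with the authors' log ratios, and 100% with the median over probe sets, which contains the second probe set. The 5 neighbours of Drd2 at least 1.5-fold apart became 3 after quantile normalization, intensity-dependent centring, 32 added units and with the authors' log ratios, and 9 with no filter; the cause was not tested.

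Of 216 alternative values of the 24 list medians, 207 moved by less than the distance from the middle of the random range to its edge and 9 by more. The chaperone and the glutamate and GABA receptor lists lay outside the random range in all 10 settings, the main one included, and the reactive astrocyte and cortical lists in 8 of 10. Interneuron markers lay outside in 2, quantile normalization (-0.29) and intensity-dependent centring, shared striatal neuron markers in 1, the median over probe sets (0.10), and neuropeptides in 1, no filter (0.29). Of 1076 alternative values of 124 named genes other than Drd2, 1000 moved by less than the spread of genes of like signal, and 76 by more. In 7 genes the sign differed in some alternative. Of these, Arhgap39 (0.22 without shared-sequence probe sets) and Daam1 (0.12 with the median over probe sets) had ratios beyond that spread, and turned because other probe sets of the gene were higher. The others, with ratios inside it, were Cxcl2, Eps8 and S100a8 (-0.3, -0.2 and -0.2 with the authors' log ratios), Adk and Rgs4.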

Other observations

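Several neuropeptide precursors differed in both directions, and as a list they had a median of -0.00 over 16 genes (percentile 66.8). From the signals, Cartpt was at least 3.15-fold and Gal at least 2.83-fold higher in the Drd2-/- array, both absent in wild type. Pmch read 0.90, while Cck read -1.40 in the array where cortical neuron markers were also lower. The authors' deposited table calls Cartpt increased (1.6) but Gal (1.5, limits of 0.7 and 2.2) and Pmch (0.8, limits of -0.5 and 2.1) unchanged, so the bound for Gal is not firm. Interferon-induced genes had a median of -0.07 over 19 genes (percentile 14.9), with Mx1 at most -1.98, Oas2 at least 1.11 and Gbp3 at 0.94, all from signals of at most 161 units. The authors' deposited table gives Mx1 -2.3 (limits of -4.1 and -0.5), Oas2 0.2 and Gbp3 0.4, all called unchanged. The bounds for Mx1 and Oas2 are therefore not firm. Complement and MHC genes had a median of -0.16 over 12 genes (percentile 12.4), with H2-K1 at -0.55, Psmb9 at -0.35 from a signal not called present in Drd2-/-, C1qc at -0.31 and H2-D1 at -0.31. The authors' deposited table gives -0.3 for the same H2-K1 probe set and -0.1 for Psmb9, with limits of -0.5 and 0.2, both called unchanged. Of the blood cell transcripts, 4 were detected, with a median of 0.04 (percentile 61.6): Ngp at least 0.72 from the signals (0.5 in the authors' deposited table), S100a8 0.36 (-0.05 after intensity-dependent centring, -0.2 in the authors' deposited table), Car2 -0.30 and Bpgm -0.28.

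For the lower cortical neuron markers the test of a second gene set and that of centring were set before their results were seen, but the second set was written after the list's own values were seen, in place of a test on a subset of that list. More cortex in the wild-type tissue piece may account for the pattern: 15 detected cortical and claustral genes outside the list had a median of -0.34 (percentile 0.02, random range -0.23 to 0.12), with 13 below 0, Nrn1 at -1.70, Cplx3 at most -1.03 and Rprm at -0.67. Of these 15, 13 were also present in the Drd2-/- array, as were 9 of the 12 list members; the brightest of the second set, Zbtb18 and Vsnl1, read -0.03 and -0.17. After intensity-dependent centring the list median was -0.39, below its random range of -0.25 to 0.13. That test could hardly come out otherwise, since centring moves the list and its signal-matched random lists alike, so it adds nothing. A scaling difference that varies with signal is argued against only by the matching itself, as the list lay below lists of like signal before centring (percentile 0.02). An effect of genotype on these genes stays open and untested, since each genotype was 1 dissected piece.

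The 2 deposited tables give the same signals to opposite genotypes, and both tests of this were chosen after the Drd2 values were seen. Exchanged genotype names in the comparison table are a candidate explanation in line with the Drd2 log2 ratio of -6.88 by the sample labels. Exchanged labels of the 2 samples are argued against by the same value, because they would place the Drd2 signal of 3234.8 units in the Drd2-/- tissue. This rests on 1 probe set of 1 gene, and no other label was at hand to check it.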
